A study of Homo sapiens with 20 samples.

How the data were processed

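The measurements were 20 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from IMR90, an established line of human lung fibroblasts. Antibodies were directed against HA, a short epitope tag fused to a protein so that it can be pulled down, against H3K9me3, a histone mark of silent chromatin, and against P65, the RELA subunit of the transcription factor NF-kB. Per the labels' protocols, cells were fixed with formaldehyde and flash frozen, and chromatin was sheared by sonication, immunoprecipitated, tagmented on the beads, amplified by PCR and sequenced as paired ends. The labels' protocols state that an input fraction was kept aside, and whether it entered the peak calls is not given in the sources used here.

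Each library came as 1 peak list, so peaks were called per library and not on pooled replicates. Per the submitters' processing notes, the authors used FastQC, Trimmomatic, Bowtie2, Picard and MACS2, with the build hg19, and no versions were given there. The deposited lists hold 3 columns, which are the chromosome, the start and the end of each peak. They carry no height, fold, score or p-value, and no read total, so the sequencing depth behind each list is unknown and no peak could be weighed by its strength. The number of peaks and the bases they cover stand in for depth below, and both also move with the calling settings. Coordinates are given counted from 1 on hg19.

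The lists of the EC1 set and of the EC2 set were not made alike. In the EC1 set the H3K9me3 lists held short peaks with a median width from 194 to 206 bp and covered 3.43 to 8.24 Mb. In the EC2 set the H3K9me3 lists held longer peaks with a median width from 1196 to 1497 bp and covered 333 to 540 Mb. The smallest gap between neighbouring peaks was 197 bp in each H3K9me3 list of the EC1 set and 689 to 725 bp in the EC2 set. The HA and H3K9me3 lists of the EC2 set held no peak on mitochondrial DNA, and every other list held at least 1. H3K9me3 was therefore compared only within a set, each controller against the baseline libraries of its own set.

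Groups were read from the treatment label of each sample, and 9 groups had 2 libraries and 2 groups had 1. The H3K9me3 baseline labels name a controller's set and were read as cells that had not received it, which the labels do not spell out. The P65 baseline label names neither a set nor a controller. The P65 label that names stimulation together with EC1 was read as the stimulated control of the EC1 experiment. This was by analogy with the H3K9me3 baseline labels, which are built the same way. Another P65 label names stimulation and no controller. Its library was put in the EC2 set as the stimulated control of the P65 library with EC2, which the labels do not state. The P65 libraries of cells given EC1 carry an extra term, E1, that the labels do not explain, and they do not say whether those cells were stimulated. Neither the stimulus nor the time point of each library is given by the labels. Nothing in the labels says that replicates came from separate cultures, so p-values and spreads measure only the difference between these libraries, which may be technical.

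Peaks on chromosomes 1 to 22 and X were kept. Peaks of the libraries compared were merged into regions where they overlapped by at least 1 base. A site of a group is a region with a peak in both of its libraries. A gained region has a peak in both libraries of a controller and in neither baseline library, and a lost region is the reverse. The same count was made for each other split of the 4 libraries into 2 and 2. Chance overlap was taken from 1000 circular shifts of 1 list along each chromosome, with the furthest peak end in any list as the length, and 200 shifts for the alternatives. The permutation p from these shifts is one-sided. Differences between 2 and 2 libraries were tested with an exact two-sided permutation test, which cannot go below 0.333. Shares of sites were compared with Fisher's exact test, two-sided. Sites are not replicates, so these tests compare the lists at hand. Intervals on shares are exact 95% binomial intervals (Clopper-Pearson) and cover counting error only. The CXCL window is chromosome 4 from 74 to 75 Mb, a stretch of 1 Mb that holds the cluster of CXC chemokine genes, and it was ranked among all 1 Mb bins. The gene order was taken from a RefSeq gene table of assembly GRCh38, from which no coordinate was used.

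The groups, the window, the tests, the rule for naming and the alternatives were fixed before the data were examined. The naming rule asked for each peak in the CXCL window by position and nearest gene, for the 10 strongest sites of each set, and for members of fixed gene lists near a start. No annotation on hg19 was used here and the lists have no strength column, so the promoter test of the gene lists was not run. Sites are named by position, apart from the placements that follow. The 4 P65 sites placed at the start of a CXC gene were placed from general knowledge of the locus, after their values were seen. The EC1 site at the start of CXCL8 and the EC2 site upstream of CXCL8 were likewise placed from general knowledge. Also chosen after the first results were seen were the shares of HA sites with H3K9me3, the same shares at sites of the other controller, the coverage around HA sites, and the P65 sites called in all 3 stimulated libraries. Coverage was read every 250 bp out to 10 kb on either side of the midpoint of an HA site. Alternatives were an overlap of at least 50% of the shorter peak, autosomes alone, each replicate left out, a window of 500 kb, peaks merged across gaps of 1 kb, and a fit within replicate numbers.

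Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The counting was tested on simulated lists of randomly placed peaks. Lists with planted sites were as long as the real ones, and planted sites overlapped by construction, so recovery checks the counting alone. Of 200 planted shared sites, 100% were recovered at the list lengths of HA with EC1 (5911 and 9845 peaks) and at those of HA with EC2 (1054 and 8439 peaks). For H3K9me3 gained with EC1, at 34250 and 13666 peaks in the 2 controller lists, 98.5% of 200 planted regions were recovered. In 40 pairs of independent lists, the shift test gave a p under 0.05 in 1 pair. These pairs matched no real list in length and had fewer shifts, so they do not give the error rate on the real lists.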

Results

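IMR90 lung fibroblasts were profiled with and without a pair of epigenomic controllers, EC1 and EC2, which the labels tie to CXCL, the CXC chemokine genes. Epigenomic controllers are proteins made in the cell from delivered mRNA and built to change chromatin at a chosen locus. The 20 peak lists fall into 11 groups. HA was mapped in cells given EC1 (n = 2) or EC2 (n = 2). H3K9me3 was mapped in cells given each controller and in a baseline group for each (n = 2 in all 4 groups). P65 was mapped at baseline (n = 2), after stimulation in the EC1 set (n = 2), with EC1 (n = 2), after stimulation in the EC2 set (n = 1) and with EC2 under stimulation (n = 1). Read depth is unknown, so list length is given in its place. The HA lists held 5911 and 9845 peaks with EC1, and 1054 and 8439 with EC2. The H3K9me3 lists held 34250 and 13666 peaks with EC1 against 31348 and 26603 at its baseline. In the EC2 set they held 166383 and 188978 peaks with EC2 against 162268 and 144752 at baseline.

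The first comparison asked where the tagged controllers were called on the genome. EC1 was called at 4941 sites in both libraries and EC2 at 1047, and the site lists of the controllers were almost separate, with 7 sites in common. No HA library came from cells without a controller, so reproducible unspecific signal of the antibody cannot be set apart from sites of the controller. In the CXCL window, EC1 had 4 sites, and 1 of them, at 74,605,285-74,606,444 on chromosome 4 (hg19), spans the start of CXCL8, the gene for the neutrophil attractant interleukin-8. The other EC1 sites there lay at 74,117,905-74,118,813, 74,177,357-74,177,893 and 74,573,721-74,574,298. EC2 had 1 site in the window, at 74,591,519-74,592,104, upstream of CXCL8. The second EC2 library alone also had a peak at 74,606,141-74,606,433, inside the EC1 site at CXCL8, and further peaks at 74,124,642-74,124,855 and 74,982,681-74,982,991.

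Circular shifts gave a mean of 15.2 shared sites for EC1 and 2.06 for EC2, so both counts lie far above chance (permutation p = 0.001 for each, the smallest that 1000 shifts can give). The EC1 libraries overlapped in 83.7% of the shorter list and 50.2% of the longer. For EC2 these shares were 99.4% and 12.4%, because the second list was far longer. The 7 sites common to EC1 and EC2 compare with 1.92 by chance (permutation p = 0.00799), and this count depends on the short list. It was 66 without the first EC2 library, against 12.3 by chance, and 11 without the first EC1 library. The window was not among the bins richest in HA peaks. It ranked 360 and 591 among 1 Mb bins in the EC1 libraries and 184 and 620 in the EC2 libraries, with 4.5 ± 0.71 (SD, n = 2) and 2.5 ± 2.1 (SD, n = 2) peaks.

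**Figure D1:**
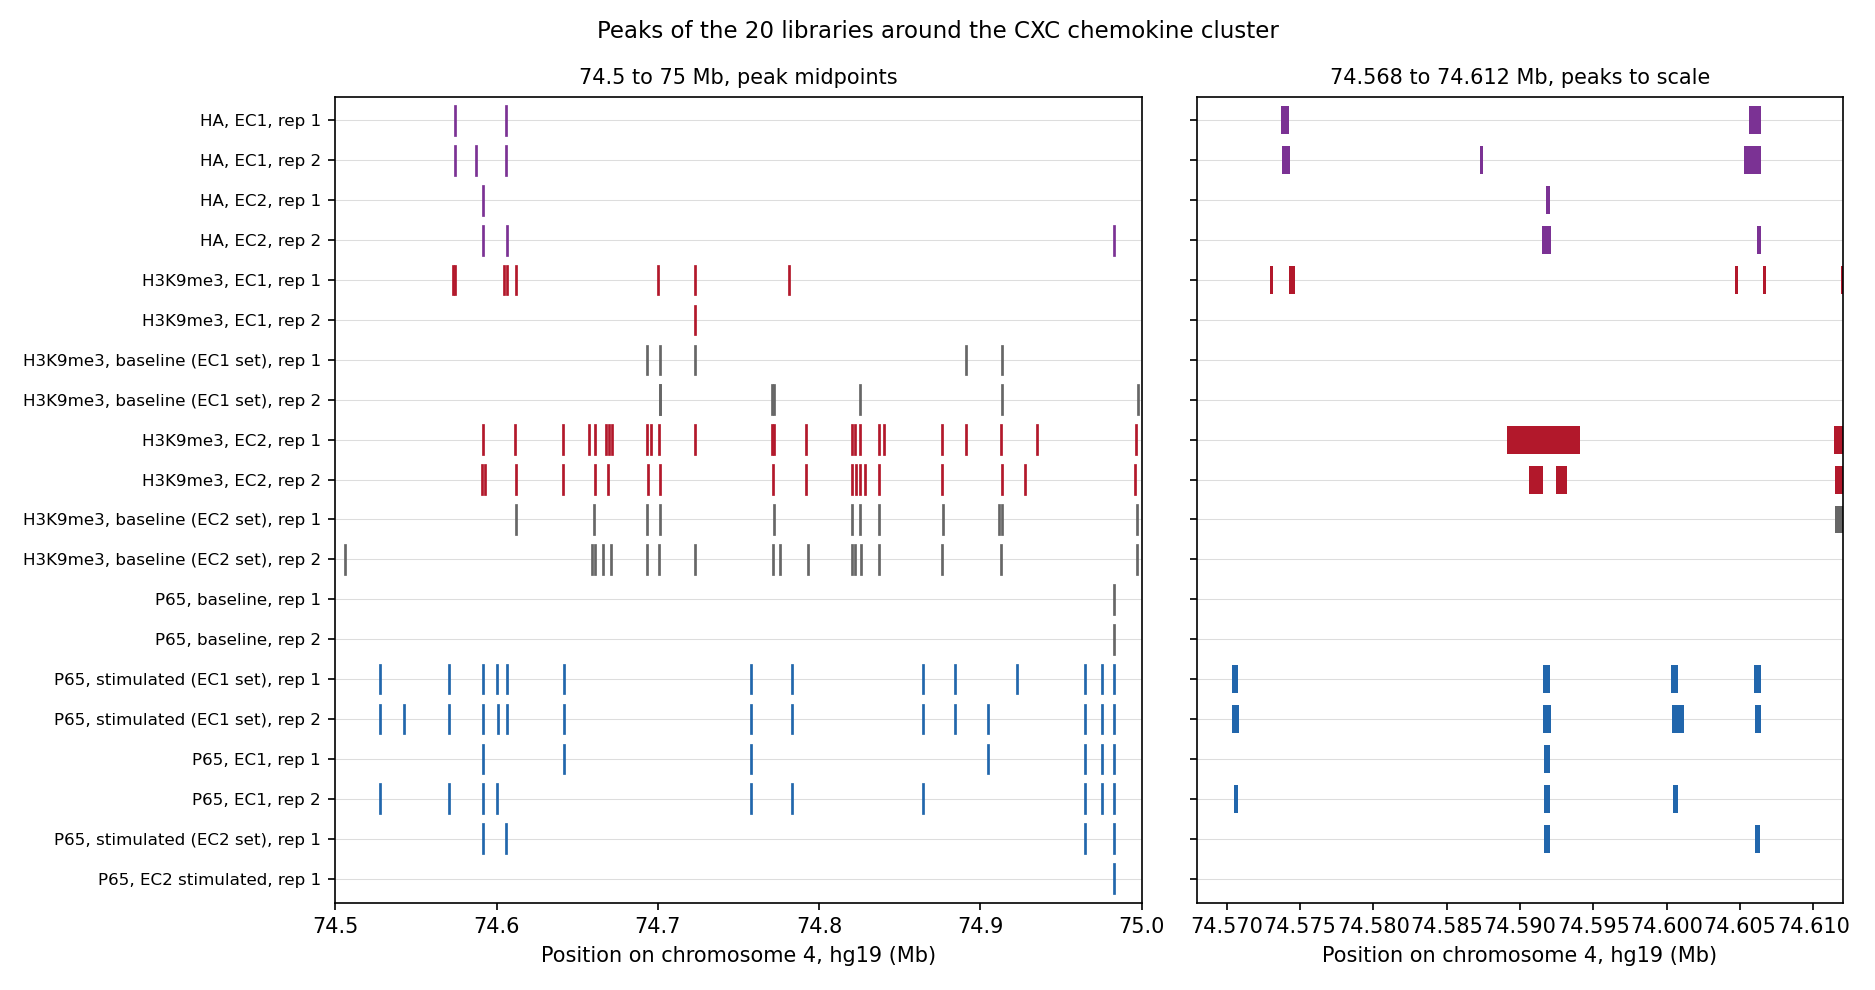
Peaks of all 20 libraries on chromosome 4 (hg19, position in Mb), 1 line per library; purple is HA, red is H3K9me3 with a controller, blue is P65 and grey is any baseline library. The left panel marks peak midpoints across the CXC cluster and the right panel draws peaks to scale around CXCL8. There the H3K9me3 peak from 74,589,103 to 74,594,062 in the first EC2 library covers the HA site of EC2. The second EC2 library has peaks at 74,590,584-74,591,557 and 74,592,421-74,593,216, which leave the centre of that site uncovered.

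The next comparison asked whether H3K9me3 was called at the controllers' sites. With EC1, 29.8% (95% interval 28.5 to 31.1) and 12.2% (11.3 to 13.1) of the 4941 EC1 sites overlapped an H3K9me3 peak in the 2 libraries, against 2.04% (1.67 to 2.48) in each of the baseline libraries. With EC2, 72.3% (69.5 to 75) and 64.8% (61.8 to 67.7) of the 1047 EC2 sites did, against 5.25% (3.98 to 6.78) and 7.74% (6.19 to 9.52) at baseline. At sites of the other controller, neither set had both controller libraries above both baseline libraries. EC2 sites overlapped H3K9me3 in 0.478% and 0.287% of cases in the EC1 libraries, against 0.573% in each baseline library. EC1 sites did so in 7.67% and 5.57% of cases in the EC2 libraries, against 4.09% and 7.23% at baseline.

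Both controller libraries lay above both baseline libraries in each set, and an exact permutation test of 2 against 2 cannot go below p = 0.333. Against their own circular shifts, EC1 sites carried H3K9me3 35.1 and 35.5 times as often as chance in the EC1 libraries and 2.64 and 3.13 times in the baseline ones. EC2 sites did so 3.60 and 4.08 times as often as chance with EC2, and 0.376 and 0.381 times at baseline, where these sites were poor in the mark. EC1 sites were also poor in the mark in the baseline libraries of the EC2 set, at 0.301 and 0.363 times chance. The baseline libraries of the 2 sets thus went opposite ways at EC1 sites. The coverage was narrow. With EC1 it was 15.3% and 5.59% at the midpoints of HA sites, 1.15% and 0.364% at 1000 bp before them, and at 8 to 10 kb it averaged 0.237% and 0.0753%. With EC2 it was 68.0% and 59.2% at the midpoints, 46.2% and 33.8% at 1000 bp before them, and 7.74% and 5.62% at 8 to 10 kb, where the baseline libraries averaged 3.82% and 7.24%. Baseline coverage in the EC1 set also rose at the midpoints of EC1 sites, to 1.34% and 1.36%. At 8 to 10 kb those baseline libraries averaged 0.195% and 0.157%.

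**Figure D2:**
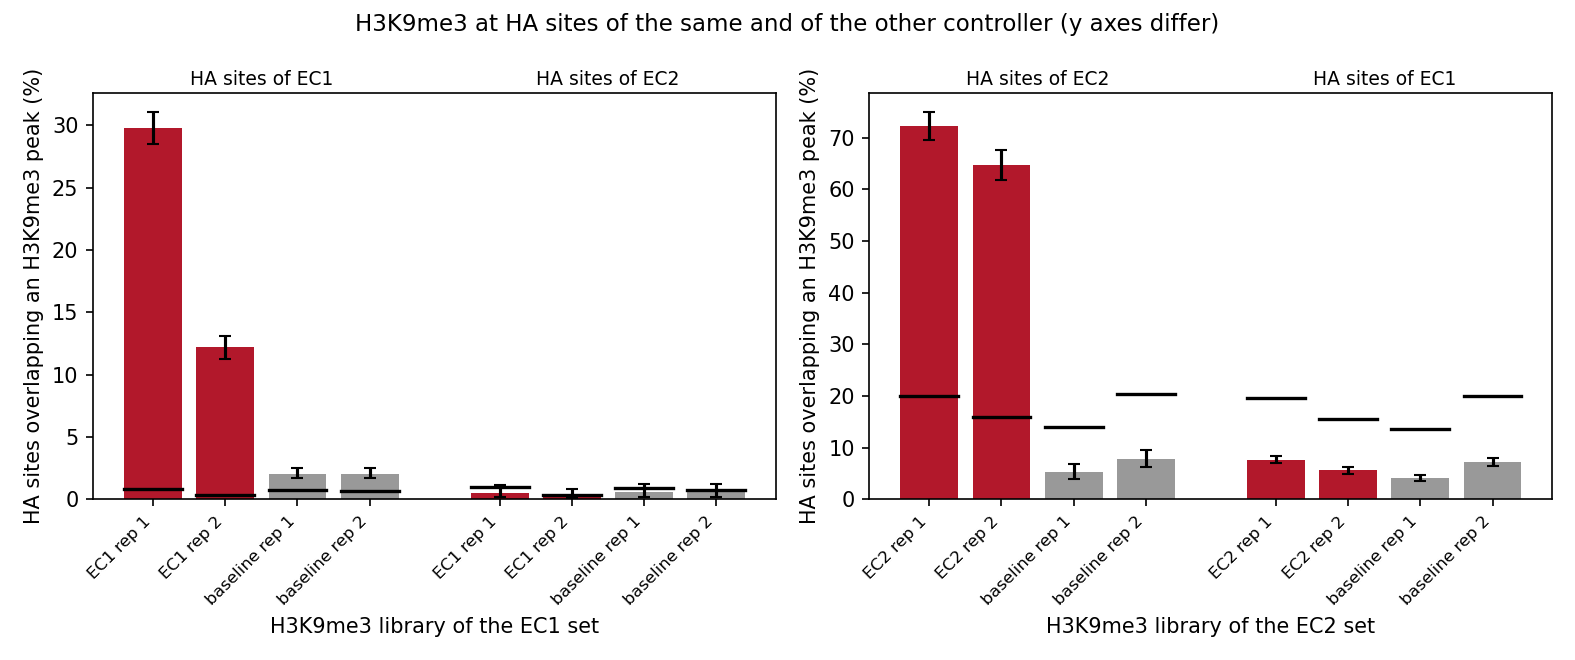
Percent of HA sites that overlap an H3K9me3 peak, 1 bar per H3K9me3 library, with exact 95% binomial intervals as error bars and the mean of circular shifts as black lines; red bars are controller libraries and grey bars are baseline. In each panel the 2 red bars at the controller's own sites, up to 29.8% for EC1 and 72.3% for EC2, stand above all others.

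**Figure D3:**
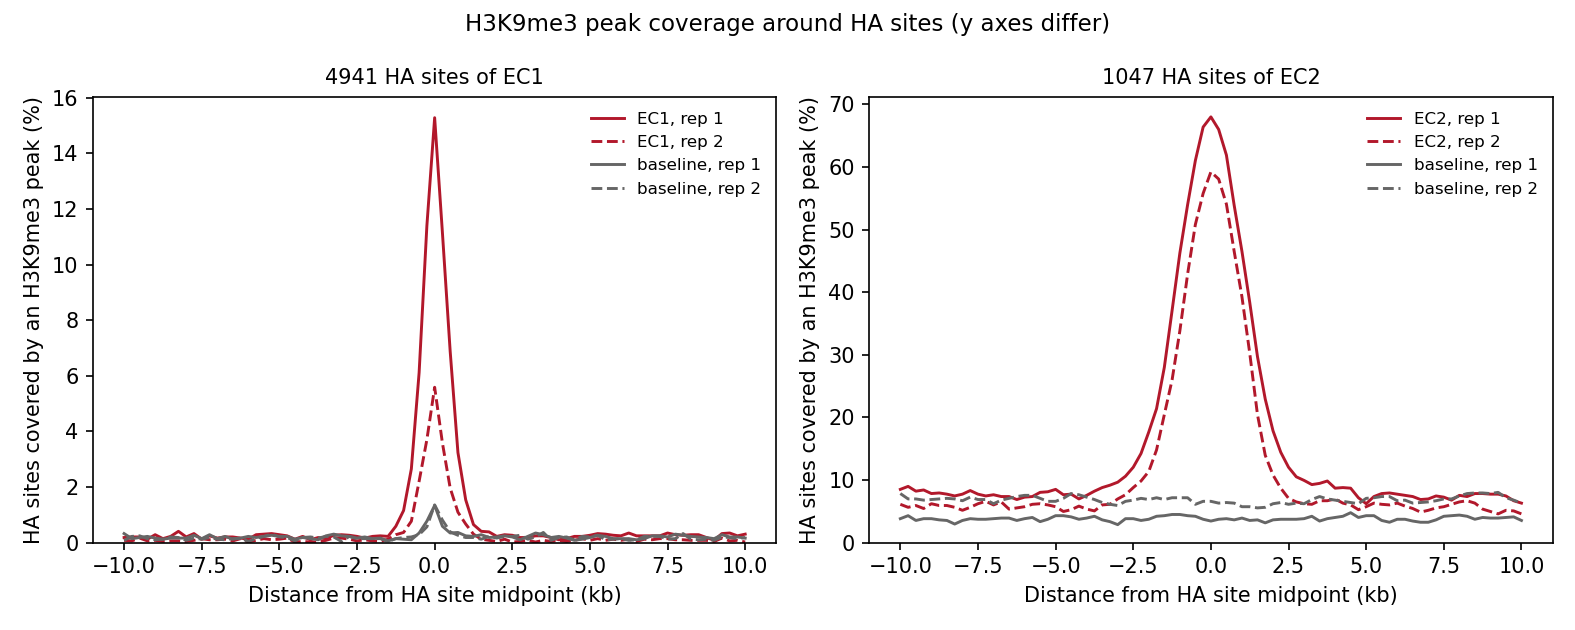
Percent of HA sites covered by an H3K9me3 peak (y axis) against the distance from the site's midpoint in kb (x axis), 1 line per library, with red for the controller and grey for baseline. With EC2 the 2 red lines reach 68.0% and 59.2% at the midpoint, and they average 7.74% and 5.62% at 8 to 10 kb, against 3.82% and 7.24% for the grey lines.

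Counted over the whole genome, regions of H3K9me3 that appeared in both EC1 libraries and neither baseline library numbered 1505, and 2652 were lost. Of the gained regions, 480 (31.9%) overlapped an EC1 site, and of the lost regions 3 (0.113%) did. With EC2, 7279 regions were gained and 2013 lost, and 547 of the gained (7.51%) and 0 of the lost overlapped an EC2 site. Shifts gave 0.147% for EC1 and 0.065% for EC2 (permutation p = 0.001 for each, the smallest possible). In the other splits of the 4 libraries, at most 0.5% of regions overlapped an EC1 site and at most 0.0486% an EC2 site.

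The counts of gained regions themselves did not stand apart from other splits of the libraries. In the EC1 set the other splits gave 3538, 2400, 598 and 443 exclusive regions, and in the EC2 set 12604, 3211, 2057 and 582. Leaving out 1 library raised the counts, since fewer lists then have to share or lack a region. Without the first or second EC1 library there were 4102 and 16488 gained regions, and without the first baseline library 2435. For EC2 the counts were 17584 and 27936 without the first or second EC2 library and 25824 without the second baseline library. The share of gained regions at EC1 sites was then 13.0%, 8.65% and 20.2%. The share at EC2 sites was 3.11%, 2.17% and 2.27%, and it rose to 28.1% without the first HA library, whose list was the short one. All of these shares stayed above their shift means.

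Among the 547 H3K9me3 regions gained at EC2 sites across the genome, 1 lay in the CXCL window, at the EC2 site upstream of CXCL8. The gained region, 74,589,103-74,594,062 and 4960 bp long, was 1 peak in the first EC2 library, and in the second it was a pair of peaks on either side of the HA site's centre, at 74,590,584-74,591,557 and 74,592,421-74,593,216. Other gained regions with EC2 were 74,640,406-74,642,375 and 74,791,579-74,792,157, and 74,420,150-74,420,479 was lost. With EC1, no window region was gained in both libraries. The first EC1 library had short peaks on either side of the HA site at CXCL8, at 74,604,644-74,604,850 and 74,606,597-74,606,806, and beside the HA site at 74,573,721-74,574,298, at 74,572,977-74,573,169 and 74,574,247-74,574,660. It also had a peak at 74,118,877-74,119,199, 63 bp from the HA site at 74,117,905-74,118,813. The second EC1 library, with the shortest H3K9me3 list, had none of these, and neither had the baseline libraries of its set. Regions at 74,701,088-74,701,384 and 74,912,921-74,913,230 were lost with EC1.

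Over the whole window, H3K9me3 covered 43345 and 26404 bp with EC2 and 15970 and 24305 bp at baseline. The difference of means, 14737 bp, had an exact permutation p = 0.333, the smallest that 2 against 2 libraries allow. It was 6266.5 bp without the first EC2 library and 23207.5 bp without the second, and it lay at percentile 92.0 of 2866 bins. With EC1 the mark covered 2055 and 515 bp against 1427 and 2495 bp, a difference of -676 bp (exact permutation p = 0.667) that was smaller than the spread between replicates. It was 94 bp, with the sign turned, without the second EC1 library, -1446 bp without the first, and -1210 and -142 bp without the first or second baseline library.

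P65 binding after stimulation was compared with baseline, where the NF-kB subunit is known to stay mostly outside the nucleus. The P65 lists held 406.5 ± 78.5 peaks (SD, n = 2) at baseline and 12589.5 ± 4557 (SD, n = 2) after stimulation in the EC1 set. Both stimulated libraries of that set lay above both baseline ones. The P65 baseline label names no set, so a difference between sets cannot be told apart from stimulation here. Sites called in both stimulated libraries and neither baseline library numbered 6500, the reverse count was 0, and other splits of the 4 libraries gave 5 to 34. Almost all of the 174 baseline sites (167, or 96.0%) were also stimulated sites. In the CXCL window the count went from 1 peak in each baseline library to 14 and 15. The baseline peak lay within 74,982,521-74,983,096, a site that every P65 library called. Among the 13 window sites of both stimulated libraries, 74,605,974-74,606,464 lies at the start of CXCL8, 74,864,289-74,864,596 at that of CXCL5 and 74,964,674-74,965,288 at that of CXCL2, which encode chemokines that draw neutrophils. A peak at the start of CXCL3, 74,904,157-74,904,653, was called in the second stimulated library of the EC1 set and not in the first. Without the first stimulated library, the count of 6500 became 15317, since the second list was the longest.

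With EC1, the P65 lists were shorter than the stimulated lists of the EC1 set, and the site at the start of CXCL8 was among those missing. The stimulated library of the EC2 set held fewer peaks still, 2391, so list length varied widely among stimulated libraries. The EC1 lists held 3289 and 2939 peaks, and 1656 sites were in both, of which 94.3% were stimulated sites and 9.84% (163) baseline sites. With only 174 baseline sites in all, the baseline share had to be low on list length alone. Of the 6981 sites of both stimulated libraries, 3760 (53.9%) were in neither EC1 list, 1576 (22.6%) in both and 1645 in 1. In the window, 5 of 13 sites were called in both EC1 libraries and 6 in 1. The absent ones were 74,605,974-74,606,464, which lies at the EC1 site spanning the start of CXCL8, and 74,883,902-74,884,235. The sites at CXCL2 and at 74,591,564-74,592,100 were called in both EC1 libraries, and that at CXCL5 in the second alone. The first EC1 library also had a peak at the start of CXCL3, at 74,904,295-74,904,496.

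Window sites were thus absent less often (15.4%, interval 1.92 to 45.4) than sites elsewhere (53.9%, interval 52.8 to 55.1), with an odds ratio of 0.155 (interval 0.0167 to 0.713) and p = 0.00909 in Fisher's exact test. This rested on the second EC1 library, without which the odds ratio was 0.631 (Fisher's exact p = 0.399). It was 0.0792 without the first stimulated library. Among 1719 sites called in all 3 stimulated libraries, 1 of 4 in the window and 21.4% of 1715 elsewhere were absent, and the odds ratio turned to 1.22 (Fisher's exact p = 1). Window peaks per library numbered 8.5 ± 2.1 with EC1 and 14.5 ± 0.71 in the stimulated libraries of the EC1 set (SD, n = 2 each). The difference was -6 peaks, with an exact permutation p = 0.333, the smallest possible. The stimulated library of the EC2 set had 4 window peaks.

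Across the genome, no difference in P65 absence between EC1 sites and other sites was detected. Of the stimulated sites at an EC1 site, 98 of 192 (51.0%) were absent from both EC1 lists, against 53.9% of 6789 other sites (odds ratio 0.890, interval 0.661 to 1.2, Fisher's exact p = 0.463). Among sites called in all 3 stimulated libraries these shares were 9 of 38 (23.7%) and 359 of 1681 (21.4%), with an odds ratio of 1.14 (interval 0.471 to 2.51, Fisher's exact p = 0.692).

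With EC2 under stimulation, P65 was called at 565 peaks, against 2391 in the stimulated library of the EC2 set. The label of that stimulated library names no controller, so its pairing with the EC2 library is a reading of the labels. In the window the stimulated library had 4 peaks, and the EC2 library called 1 of them, 74,982,601-74,983,039, the site also present at baseline. Absent were 74,591,640-74,592,043, at the EC2 site, 74,606,006-74,606,331 at the start of CXCL8 and 74,964,804-74,965,139 at that of CXCL2. The share absent was 75% in the window (interval 19.4 to 99.4) and 81.0% of 2387 peaks elsewhere (interval 79.3 to 82.5). A list of 565 peaks can overlap only a minority of 2391, so most had to be absent on list length alone. Of the 565 peaks with EC2, 80.7% overlapped a peak of the stimulated library. At EC2 sites 13 of 14 peaks were absent (92.9%, interval 66.1 to 99.8), against 80.9% of 2377 others. With 1 library per group, these values compare lists and carry no test across conditions.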

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

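Among the alternatives given here, those chosen only after the data were seen were the gained regions within 2 kb of an HA site, the sites also in the stimulated library of the EC2 set, and the crossed pairing. Of 89 alternatives, 73 kept the direction and the call or moved by little, 13 moved a value, 2 turned a sign and 1 ended a call. The sites shared by EC1 and EC2 numbered 4 with an overlap of at least 50%, and 5 to 66 with a replicate left out. HA peaks per library were 2.5 for EC1 in a 500 kb window, and for EC2 in the 1 Mb window 1 to 4 with a replicate left out. Gained H3K9me3 regions ran from 2030 to 16488 for EC1 and from 8690 to 27936 for EC2 with a replicate left out, and stimulated P65 sites from 6567 to 15317, in each case because fewer lists had to agree. The covered length with EC1 ran from -1446 to 94 bp, so its sign rests on 1 library. The odds ratio of absent P65 sites ran from 0.0792 to 0.631 (Fisher's exact p from 8.19e-06 to 0.399) and was 1.22 at sites also in the stimulated library of the EC2 set, where 4 window sites are left. The cause was not tested.

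The gained share at HA sites kept its call in every alternative run. It went from 8.65% to 37.6% for EC1 and from 2.17% to 28.1% for EC2 with a replicate left out, and was 40.2% and 8.0% within 2 kb. With a replicate block, the differences of -676 bp, 14737 bp and -6 peaks had exact sign-flip p of 1, 0.5 and 0.5, with 0.5 the smallest possible. Libraries with the same number did not deviate together (correlation over bins 0.0536 for H3K9me3 in the EC1 set and 0.0566 for P65). In the EC2 set it was -0.425, and the crossed pairing gave an exact sign-flip p = 0.5, with no call either way. Stricter peaks and lists of equal length were not run, since the lists have no strength column, and the promoter test was not run. Unknown depth limits each statement that a peak is absent.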

Other observations

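The tests on how much of the genome each list covers were chosen only after the result was seen, as were the comparisons by chromosome and by the number of HA libraries with a peak.

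P65 sites after stimulation were spread unevenly over the chromosomes. Relative to length, chromosomes 17 and 19 held 1.99 and 2.03 times their share of the 6981 sites and X held 0.137 times its share, with 49 sites. H3K9me3 regions gained with EC2 were over-represented on X for its length (2.24 times its share, 832 regions), and so were regions lost with EC2 (2.96 times, 304 regions). The share of X among all H3K9me3 regions is not given here, so these ratios do not show that changes concentrated on X. In the EC1 set X was close to its share, at 0.936 for gained and 1.05 for lost regions. The controllers were also called at stimulated P65 sites more often than shifts give. EC1 sites overlapped them in 192 of 4941 cases (3.89%, against a mean of 11.5 sites by chance) and EC2 sites in 42 of 1047 (4.01%, against 2.57), with a permutation p = 0.001 for each, the smallest possible. EC1 sites overlapped H3K9me3 in both baseline libraries of their set at the same permutation p. The shifts ignore where peaks tend to be called, so this p does not tell a link with P65 from shared peak-rich sequence.

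HA regions called in the second library alone carried H3K9me3 more often with the controller than at baseline. The 7392 regions of the second EC2 library alone overlapped H3K9me3 in 39.1% and 32.7% of cases with EC2, against 5.97% and 9.46% at baseline. The 4903 regions of the second EC1 library alone did so in 11.4% and 4.49% of cases with EC1, against 3.22% and 3.14%. The 965 regions of the first EC1 library alone overlapped H3K9me3 in 11.5% (interval 9.56 to 13.7) and 4.56% (3.33 to 6.07) of cases with EC1, against 4.46% and 4.35% at baseline. The raw share in the second H3K9me3 library was thus level with baseline there. Its list was shorter, with 13666 peaks against 31348 and 26603 at baseline. Shares relative to chance are not given for these regions, so a difference allowing for list length is left undecided. The first EC2 library alone had 6 regions, too few to compare. The shares in regions of the second library alone are below those at sites of both libraries, 72.3% and 64.8% for EC2 and 29.8% and 12.2% for EC1.

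The first pattern weighed is the P65 peak at the start of CXCL8, absent from both EC1 lists at a place where EC1 itself was called. Shorter P65 lists with EC1 could account for it, since 21.4% of the sites called in all 3 stimulated libraries are absent from both. That share lies between the 50% set as the mark of this cause and the 5% set against it. A local loss where EC1 was called is a biological candidate explanation, and its test gave an odds ratio of 1.14, with an interval too wide to decide. Both remain open, and they cannot be told apart at a single site without signal heights. Whether the EC1 cells were stimulated, and at what time point they were taken, is not given by the labels. A difference in either cannot be told apart from an effect of EC1.

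The second pattern is the set of H3K9me3 peaks beside 3 of the 4 EC1 sites in the window, those at CXCL8, 74,573,721-74,574,298 and 74,117,905-74,118,813, seen in 1 EC1 library of 2. A general gain of H3K9me3 near EC1 sites may account for it: within 2 kb of them, the lower ratio to chance of the EC1 libraries was 6.81 times the higher ratio of the baseline libraries. The second library had a ratio to chance 7.53 times that same baseline ratio, from a list under 50% as long, so its lack of peaks at these sites may reflect the shorter list. HA signal carried over into the H3K9me3 libraries stays open. Of EC1 sites with an H3K9me3 peak within 2 kb, 37.9% and 30.7% in the EC1 libraries had their midpoint inside a peak. This lies between the 50% set for this cause and the 20% set against it. The baseline libraries, read here as cells without the controller, gave 27.4% and 29.3%, so this measure separates the cases poorly. It also depends on the sites counted. Among sites that overlap a peak, the midpoint was covered at 755 of 1471 and 276 of 602 in the EC1 libraries. At baseline it was covered at 66 of 101 and 67 of 101, a higher share than with EC1.

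More H3K9me3 regions were gained than lost with EC2, the third pattern, and how much of the genome each list covers could add to the count, because the 2 lists of longest covered length, 1 with EC2 and 1 from baseline, shared 12604 exclusive regions. The 4 splits that pair an EC2 list with a baseline list followed the summed covered length, with 12604 regions at 1060 Mb, 3211 at 917 Mb, 2057 at 853 Mb and 582 at 710 Mb, and the baseline pair gave 2013 at 873 Mb, while the EC2 pair, with 7279 at 897 Mb, gave more than the split at 917 Mb. The EC2 lists also hold the most peaks, so list length stays open for the count. The lists of longest covered length shared only 1 exclusive region at an EC2 site, against 547 for the EC2 libraries, which argues against covered length for the gained regions at EC2 sites. For that part, 7.51% of gained regions, placement of the mark by the controller is a hypothesis these values fit, found and tested on the same data. Carried-over HA signal is also open. Of EC2 sites with an H3K9me3 peak within 2 kb, 90.7% and 84.6% had their midpoint inside a peak with EC2, and 35.0% and 47.9% at baseline.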
